A study of Mus musculus with 8 samples.

How the data were processed

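Undifferentiated spermatogonia, the germline cells of the testis that include the spermatogonial stem cells, were sorted from adult mice on E-cadherin and CD49f (the product of Itga6) with exclusion of c-Kit, per the labels' protocols. Total RNA was amplified by the single primer isothermal method and sequenced as 8 libraries, 4 from Control mice and 4 from TAM-KO mice. TAM-KO mice carried a floxed Gilz gene (Tsc22d3) and a tamoxifen-inducible Cre recombinase expressed from the ubiquitin C promoter, and Control mice carried the floxed gene alone. Both received 2 mg tamoxifen on 2 consecutive days and were sampled 7 days later, at 6 to 8 weeks of age.

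The values are the deposited raw counts of reads per gene, 1 column per library, for 22048 protein-coding genes. Per the submitters' processing notes, the authors named featureCounts, edgeR and limma and the genome build GRCm38. Their versions, the aligner and the annotation release are not given in the sources used here. A deposited summary table gives the number of reads per library in counts by assignment class, so the share assigned, multi-mapping, ambiguous and outside annotated features could be computed. Every row of the gene table names a gene and no row was removed. The deposited table is named as non-stranded counts, so a gene and an overlapping or antisense partner are treated as not separable. Reads of near-identical copies, such as replication-dependent histones and ribosomal proteins, can map to several of them, so single copies are uncertain. The summary holds ambiguous and multi-mapping reads apart from assigned ones, so such reads may be missing from the gene counts. Coordinates come from GENCODE mouse release 21 on GRCm38, in which 21781 of the 22048 gene identifiers were found.

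Groups came from the sample labels alone. Genes were filtered with filterByExpr in edgeR 4.0.16 (R 4.3.3), libraries were scaled by TMM, and groups were compared with the robust quasi-likelihood F test over all 8 libraries, leaving 6 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg over the 14816 genes tested, with a threshold of 0.05. Log2 fold changes are TAM-KO over Control, and their standard error (SE) is the absolute log2 fold change divided by the square root of F. CPM are a gene's counts relative to the library's total: those of single genes use TMM-scaled totals, and summed CPM of gene lists use the unscaled total of all protein-coding genes. Both are given as mean ± SD over 4 libraries.

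A total of 39 gene lists (pathways, stages of germ cell development and other testis cell types) were fixed before the data were examined, as were the main test, the rule for named genes and the alternatives, apart from those named as added later. The 37 lists with at least 4 measured members were tested against all other genes with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01, and again with an estimated correlation and with fry. Fry asks whether a list moves on balance in 1 direction and does not compare it with other genes. Adjusted p-values of lists are over these 37, of which 1 is not reported here. For each list, members past the threshold were also counted with p-values adjusted over the list alone.

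Named genes are Tsc22d3; the 12 with the largest log2 fold change in each direction among called genes with a mean of at least 5 CPM, complete separation of the groups and a symbol that is no placeholder; up to 4 members with the smallest p in each list; and a fixed set of spermatogonial and TSC22 family genes. A single value was compared by an exact permutation test over the 70 assignments of 4 and 4 libraries, two-sided, whose smallest p is 0.0286.

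The tests were tried on simulated data with the libraries' own means, sizes and dispersion. With 14816 genes in the TAM-KO and Control comparison, edgeR recovered 38 of 50 genes changed 4-fold (76%), 48 of 100 changed 2-fold and 4 of 50 changed 1.5-fold, with 5 false calls. The minimum recovery required of 4-fold genes was lowered to fit this outcome after it was seen. In this simulation most 1.5-fold changes, many 2-fold changes and some 4-fold changes were therefore missed. It drew genes independently and held no library that deviated from its group as a whole.

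Replicate libraries of a group differed by 7.98 to 66.5 times the sampling noise (chi-square per degree of freedom), so none was a duplicate. The design text speaks of 4 independent sets, and the labels do not tie libraries to single animals, so p-values measure the spread between these libraries. Alternatives were DESeq2 1.42.0, limma-voom with and without library quality weights, other scalings and filters, a replicate block, a looser threshold and leaving out each library in turn. Leaving out Control replicate 1 and TAM-KO replicate 4 together, leaving Tsc22d3 out of the lists, estimating the correlation with each library left out, and removing a gene length and GC trend were added after the data were seen. Figures were drawn with matplotlib 3.10.9.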

Results

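Transcript levels were measured in sorted undifferentiated spermatogonia 7 days after tamoxifen, to ask which genes differ when Gilz is deleted in adult mice. Gilz, encoded by Tsc22d3, is the glucocorticoid-induced leucine zipper protein. There were 4 Control and 4 TAM-KO libraries. The total protein-coding count was 8462719, 9747226, 8695912 and 9961255 in Control replicates 1 to 4 and 10670157, 9019383, 10179470 and 14079262 in TAM-KO replicates 1 to 4. Between 41.3% and 46.3% of the reads of a library were assigned to a gene.

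Tsc22d3 (ENSMUSG00000031431, GRCm38 chromosome X, 140539528 to 140600659, minus strand) was lower in every TAM-KO library than in every Control library. Its level was 195 ± 22.8 CPM (SD, n = 4) in Control and 66.3 ± 6.79 CPM (SD, n = 4) in TAM-KO, from 598 to 2195 reads per library. It fell 2.95-fold (log2 fold change -1.56 ± 0.12 SE, edgeR adjusted p = 0.000286), and an exact two-sided permutation test gave p = 0.0286, the smallest possible. The counts cover the whole gene, so reads from exons outside the deleted part can remain. The 3 other family members did not pass: log2 fold changes were -0.24 ± 0.12 for Tsc22d1, -0.31 ± 0.11 for Tsc22d2 and 0.44 ± 0.19 for Tsc22d4.

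Across 14816 genes, 130 differed between the groups, 101 lower and 29 higher in TAM-KO (edgeR quasi-likelihood test, Benjamini-Hochberg). Of these, 43 were at least 2-fold lower and 11 at least 2-fold higher. Among called genes with a mean of at least 5 CPM and a symbol that is no placeholder, the largest falls were in T (brachyury, a T-box transcription factor), 5.84-fold, Sez6, 5.02-fold, Ddah2, 4.27-fold, and Havcr1, 4.12-fold. Tlr3 (a receptor for double-stranded RNA), Rasl11a, Aox4, Dmrt2, Dgkk, Sidt1 and Pitpnm1 fell 2.75- to 3.48-fold. The largest rises were in the transcription factor Runx3 (2.88-fold), Cpne2 (2.73-fold), Elmsan1 (2.68-fold) and Grb10 (2.45-fold), an imprinted adaptor of insulin receptor signalling. Scube2, Lrp8, Ccng1, Met (the hepatocyte growth factor receptor), Cc2d2b, B3gnt5, Grik5 and Rnf169 rose 1.70- to 2.39-fold. All 130 called genes separated the groups completely, as did 1458 genes in all (9.84%, against 2.86% by chance). The calls come from the same values and favour such genes, so their separation is no added support. The spread of the chance share, with genes that move together, was not estimated.

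The number called depended on single libraries: it was 37, 16 and 19 without Control replicates 2, 3 and 4, 38, 27 and 80 without TAM-KO replicates 1, 2 and 3, and 415 (235 lower, 180 higher) without TAM-KO replicate 4. Upper-quartile scaling gave 196 lower and 23 higher. With the replicate number as a block, 40 were lower and 8 higher. Of the 43 named genes that were called, T, Tsc22d3, Sez6, Ddah2, Havcr1, Tlr3, Dgkk, Slc2a1 and Elmsan1 stayed called without any 1 library; the other 34 did not, and none changed sign. Because Control mice lacked the Cre transgene, the comparison holds Cre and the loss of Gilz together. With the ubiquitin C promoter, that loss need not be confined to spermatogonia. Effects of its loss in other cells cannot be told from effects within the sorted cells.

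**Figure D1:**
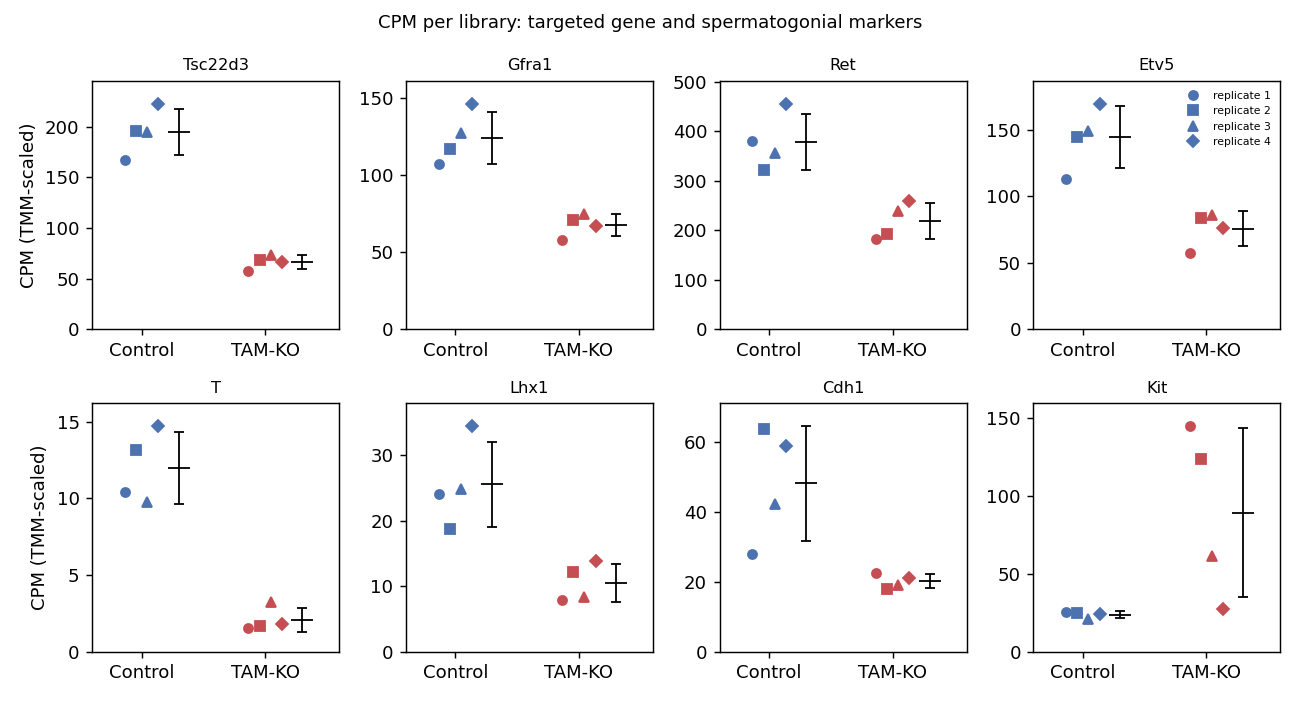
TMM-scaled CPM (linear axes from 0) of 8 genes in each of the 4 Control (blue) and 4 TAM-KO (red) libraries, with marker shape for the replicate number and a black bar for mean ± SD. Tsc22d3, Gfra1, Ret, Etv5, T, Lhx1 and Cdh1 are lower in every TAM-KO library than in every Control library. Kit is higher in every TAM-KO library than in every Control library, but ranges from 27.2 to 145 CPM within TAM-KO.

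Genes listed as markers of stem-cell-enriched undifferentiated spermatogonia were lower in TAM-KO as a group. The list also holds Cdh1 and Itga6, whose products selected all the sorted cells, and Plvap, which is in the endothelial list too. Not every member is therefore particular to stem cells. Of 26 measured markers, 9 fell, 0 rose and 17 did not pass, and 25 had a log2 fold change below 0 (median -0.86). Adjusted over the list alone, 21 fell. The GDNF co-receptor Gfra1 (ENSMUSG00000025089, chromosome 19, 58235604 to 58455909) fell from 124 ± 16.9 to 67.5 ± 7.12 CPM (SD, n = 4 each), a log2 fold change of -0.88 ± 0.13 (adjusted p = 0.0113). Its signalling partner Ret fell by 0.79 ± 0.14 on the log2 scale and the GDNF-responsive transcription factor Etv5 by 0.93 ± 0.16. The others that fell were T (ENSMUSG00000062327, chromosome 17, 8434423 to 8442496), Lhx1, Shisa6, Plvap, Sall4 and Cdh1. Nanos2 (log2 fold change -1.03 ± 0.40), Zbtb16 (-0.42 ± 0.14), Id4 (-0.37 ± 0.23) and Bcl6b (-0.31 ± 0.23) did not pass. Camera called the list lower (adjusted p = 2.66e-17), with adjusted p = 0.167 with an estimated correlation. Without Control replicates 2, 3 or 4 the members called lower were 3, 1 and 1, and without TAM-KO replicates 1 or 2 they were 2 and 2. With the replicate number as a block, 4 members were called lower. Beside this, summed spermatid marker CPM in TAM-KO replicate 4 was 2.40 times that of the next library; without it 12 stem-cell-enriched markers fell, and without Control replicate 1 as well, 16.

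The genes behind the sort gate differed among themselves. Cdh1, which encodes the E-cadherin used to select cells, fell from 48.3 ± 16.4 to 20.2 ± 2.08 CPM (SD, n = 4 each; adjusted p = 0.0328). Itga6, which encodes CD49f, was at 140 ± 14.3 CPM in Control and 144 ± 16.6 CPM in TAM-KO (adjusted p = 0.871); its log2 fold change of 0.05 turned to -0.0055 with upper-quartile scaling. Kit, whose product was used to exclude cells, was at 23.8 ± 2.12 CPM in Control and 89.2 ± 54.4 CPM in TAM-KO. The groups separated narrowly, with a highest Control value of 25.3 CPM and a lowest TAM-KO value of 27.2 CPM. Kit did not pass (log2 fold change 1.91 ± 0.48, adjusted p = 0.128), but did without TAM-KO replicate 4 (log2 fold change 2.21, adjusted p = 0.000918).

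Lists of the next germ cell stages were called in different directions by camera. Of 12 markers of transit-amplifying progenitors, 0 passed (7 at an unadjusted p under 0.05, 1 by DESeq2) and 4 fell adjusted over the list alone. Among them were Upp1 (log2 fold change -1.18 ± 0.25, adjusted p = 0.0560) and Lin28a (-0.55 ± 0.15), while Neurog3 was at -0.41 ± 0.19 and Sox3 at 0.14 ± 0.15. Camera placed the progenitor list lower (adjusted p = 0.00235), with adjusted p = 0.291 with an estimated correlation. Of 17 markers of differentiating spermatogonia, 1 fell, the cyclin gene Ccnd2 (log2 fold change -0.59 ± 0.12), 0 rose and 16 did not pass, and 13 had a log2 fold change above 0 (median 0.42). Adjusted over the list alone, 6 rose and 1 fell. Dmrtb1 (1.15 ± 0.26), Dnmt3b (0.44 ± 0.13) and Stra8 (0.42 ± 0.37) did not pass over all genes. Camera placed the list higher (adjusted p = 0.0121), with adjusted p = 0.349 with an estimated correlation, and no longer without TAM-KO replicate 1 (adjusted p = 0.0795); without TAM-KO replicate 4, 4 members rose.

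All 21 spermatid markers had a log2 fold change above 0 (median 0.66) and 0 passed, with 0 at an unadjusted p under 0.05 and 0 by DESeq2. Camera called this list higher (adjusted p = 0.0142), with adjusted p = 0.661 with an estimated correlation. The call rested on TAM-KO replicate 4, in which summed spermatid CPM was 11445 against 2435 to 4761 in the other 7 libraries; without it the median log2 fold change was -0.0012 and the camera adjusted p = 0.965. The call was also lost without Control replicate 3 (adjusted p = 0.143). Odf1, a sperm tail gene, was at 868 CPM in TAM-KO replicate 4 and at most 257 CPM in the other TAM-KO libraries. Of 18 spermatocyte markers 0 passed (3 at an unadjusted p under 0.05, 0 by DESeq2), and camera did not call the list (adjusted p = 0.201).

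**Figure D2:**
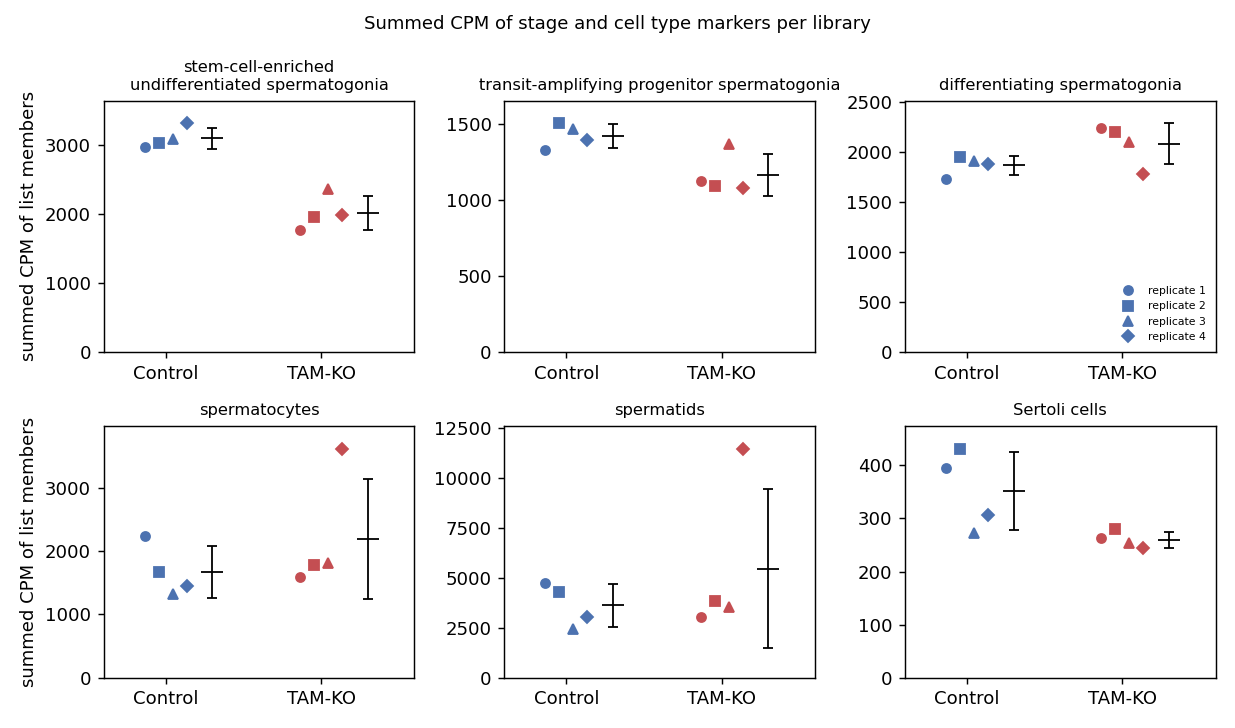
Summed CPM (linear axes from 0) of the members of 6 marker lists in each Control (blue) and TAM-KO (red) library, with marker shape for the replicate number and a black bar for mean ± SD. The stem-cell-enriched sum is 2960 to 3308 in Control and 1771 to 2353 in TAM-KO, and TAM-KO replicate 4 stands alone in the spermatid sum at 11445.

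Camera called 3 lists of somatic testis cell markers lower in TAM-KO, with few or no members passing. Summed Sertoli cell CPM was 351 ± 73.9 in Control and 260 ± 15.5 in TAM-KO (SD, n = 4 each; exact permutation p = 0.0571, adjusted 0.186). Of 19 measured Sertoli cell markers 0 passed (7 at an unadjusted p under 0.05, 0 by DESeq2), with Wt1 at a log2 fold change of -0.60 ± 0.21 (camera adjusted p = 0.00172, and adjusted p = 0.349 with an estimated correlation). Of 11 endothelial markers 1 fell, Plvap (also in the stem-cell-enriched list), and 2 adjusted over the list alone (camera adjusted p = 0.000445, and adjusted p = 0.167 with an estimated correlation). Of 13 peritubular myoid and fibroblast-like markers 0 passed (3 at an unadjusted p under 0.05, 1 by DESeq2) and 2 fell adjusted over the list alone, with Col1a1 at -0.95 ± 0.27 (camera adjusted p = 0.0273, and adjusted p = 0.498 with an estimated correlation). This call was lost without Control replicate 1 (adjusted p = 0.292), TAM-KO replicate 1 (0.0557) or TAM-KO replicate 3 (0.111), and without Control replicate 1 and TAM-KO replicate 4 together (0.146). Of 15 macrophage and leukocyte markers 0 passed (1 at an unadjusted p under 0.05, 1 by DESeq2) and 1 fell adjusted over the list alone, Mrc1 (log2 fold change -1.10 ± 0.27; camera adjusted p = 0.140, but 0.00489 without Control replicate 3 and 0.0325 without TAM-KO replicate 4; with an estimated correlation these 3 values were 0.661, 0.506 and 0.631). Only 3 Leydig cell and 1 erythroid marker were measured and 0 passed (1 and 0 at an unadjusted p under 0.05, 0 by DESeq2).

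Of 24 AKT-FOXO target genes, 4 fell, 0 rose and 20 did not pass, and 8 fell adjusted over the list alone: the transcriptional repressor Bcl6 (log2 fold change -1.15 ± 0.15), the ubiquitin ligase gene Fbxo32 (-0.87 ± 0.16), Ret and Cited2 (-0.75 ± 0.14) passed over all genes. Camera called this list lower (adjusted p = 3.09e-06), with adjusted p = 0.167 with an estimated correlation. Of 21 ERK-MAPK feedback and target genes, 2 fell, Egr2 (-1.36 ± 0.22) and Etv5, and 4 adjusted over the list alone; Dusp6, a phosphatase acting on ERK, was at -1.05 ± 0.29 and did not pass (camera adjusted p = 3.68e-05, and adjusted p = 0.349 with an estimated correlation). Of 22 GDNF and FGF receptor signalling genes, 2 fell, Gfra1 and Ret, and 5 adjusted over the list alone; Fgfr1 was at -0.55 ± 0.13 (adjusted p = 0.0632; camera adjusted p = 0.0297, and adjusted p = 0.241 with an estimated correlation). Of 27 immediate-early and dissociation genes, 1 fell, Egr2, and 2 adjusted over the list alone (camera adjusted p = 0.000875, and adjusted p = 0.167 with an estimated correlation). Of 19 WNT pathway and target genes, 2 fell over all genes and over the list alone, T and Shisa6 (camera adjusted p = 0.140). Gfra1, Ret, Etv5, Dusp6, T and Shisa6 are also in the stem-cell-enriched list. Their falls here are therefore the same changes and not separate evidence for these pathways. Without TAM-KO replicate 4 the AKT-FOXO count was 6. The GDNF and FGF list lost its camera call without Control replicate 1 (adjusted p = 0.0555) or 3 (0.0516), without TAM-KO replicate 3 (0.0509) or 4 (0.0978), and without Control replicate 1 and TAM-KO replicate 4 together (0.112).

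Of 17 glucocorticoid-response genes, 1 fell, Tsc22d3 itself, and 3 adjusted over the list alone. Mt2, a metallothionein (log2 fold change -0.63 ± 0.14, adjusted p = 0.0557), and the kinase gene Sgk1 (-0.64 ± 0.19) did not pass. Camera called the list lower (adjusted p = 0.00334; 0.0216 with Tsc22d3 left out of it), with adjusted p = 0.249 with an estimated correlation. The 4-member TSC22 family, which includes the deleted gene, was also called lower (adjusted p = 0.0273, and 0.251 with an estimated correlation); 1 member fell, Tsc22d3, and 2 adjusted over the list alone. Its call is not independent of the deletion, and was lost without Control replicate 1 (adjusted p = 0.0703), without TAM-KO replicates 1, 2 or 3 (0.0795, 0.0562 and 0.0516), and without Control replicate 1 and TAM-KO replicate 4 together (0.0781). Of 26 interferon response genes, 1 fell, Oasl2 (-0.64 ± 0.10), 2 adjusted over the list alone, and 23 had a log2 fold change below 0. Stat2 was at -0.61 ± 0.13 (adjusted p = 0.0584). Camera called the interferon list lower (adjusted p = 0.000398), with adjusted p = 0.167 with an estimated correlation. Of 14 NF-kB target genes 0 passed (3 at an unadjusted p under 0.05, 0 by DESeq2; camera adjusted p = 0.140).

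Of 40 G2/M-phase genes, 1 rose, the mitotic kinase gene Plk1 (log2 fold change 0.74 ± 0.14), 39 did not pass, 3 rose adjusted over the list alone, and 32 had a log2 fold change above 0 (median 0.27). Mki67, a proliferation marker, was at 571 ± 126 CPM in Control and 1109 ± 346 CPM in TAM-KO (adjusted p = 0.113). Camera called the G2/M list higher (adjusted p = 6.18e-05), with adjusted p = 0.400 with an estimated correlation. Over TAM-KO replicates 1 to 4, Kit was at 145, 123, 61.2 and 27.2 CPM, Mki67 at 1524, 1262, 859 and 791 CPM, and the summed G2/M list at 9599, 8771, 7107 and 6689 CPM, against 5909 to 6970 in Control. The summed S-phase list was at 4187, 4070, 3543 and 2767 CPM in these libraries, against 3185 to 3525 in Control. This order was seen after the fact and is not particular to cell cycle genes. The summed ribosome biogenesis list, which camera called lower, had it too, at 7442, 7227, 6887 and 5418 CPM. Of 35 S-phase genes 0 passed (6 at an unadjusted p under 0.05, 1 by DESeq2), with E2f8 at 0.67 ± 0.18 (camera adjusted p = 0.00599, and adjusted p = 0.624 with an estimated correlation). Of 31 replication-dependent histone genes, near-identical copies whose reads can map to several of them, 0 passed (12 at an unadjusted p under 0.05, 4 by DESeq2) and 1 rose adjusted over the list alone (camera adjusted p = 0.00172, and adjusted p = 0.623 with an estimated correlation). Without TAM-KO replicate 4, 6 G2/M, 3 S-phase and 5 histone genes rose. Without Control replicate 1 the S-phase and histone lists lost their camera calls (adjusted p = 0.0555 and 0.143), and the S-phase list also did without TAM-KO replicate 1 (0.137) or 2 (0.0883).

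Of 20 p53 target genes, 1 rose, Ccng1 (log2 fold change 1.12 ± 0.17), and 3 rose and 1 fell adjusted over the list alone. Plk2 (1.06 ± 0.22, adjusted p = 0.0523) and Phlda3 (1.80 ± 0.39, adjusted p = 0.0557) did not pass, and Cdkn1a was at 0.12 ± 0.20. Camera did not call this list (adjusted p = 0.0653), but did without TAM-KO replicate 4 (adjusted p = 0.0115, 4 members higher), with adjusted p = 0.425 with an estimated correlation. It also did without Control replicate 2 (0.0392, and 0.519 with an estimated correlation) or 3 (0.0480 and 0.506), and without Control replicate 1 and TAM-KO replicate 4 together (0.0252). Of 22 apoptosis regulators 0 passed (8 at an unadjusted p under 0.05, 1 by DESeq2) and 1 rose adjusted over the list alone; camera adjusted p = 0.895, with a sign below 0 against a median of 0.02 that turned negative under upper-quartile and total-count scaling. Of 20 unfolded protein response genes 0 passed (4 at an unadjusted p under 0.05, 1 by DESeq2), 19 had a log2 fold change above 0, and Manf was at 0.54 ± 0.15 (camera adjusted p = 0.0208, and adjusted p = 0.551 with an estimated correlation). That call was lost without Control replicate 1 (adjusted p = 0.154), without TAM-KO replicate 1 (0.110) or 2 (0.0562), and without Control replicate 1 and TAM-KO replicate 4 together (0.0638). The summed list was at 4177, 3914, 3569 and 3282 CPM in TAM-KO replicates 1 to 4, the order of Kit (145, 123, 61.2 and 27.2 CPM). This order was seen after the fact and is not particular to this list. The summed heat-shock, WNT and retinoic acid lists, which camera did not call, had it too. Of 19 heat-shock and chaperone genes 0 passed (2 at an unadjusted p under 0.05, 1 by DESeq2) and 1 fell adjusted over the list alone, Hsph1 (-0.41 ± 0.10; camera adjusted p = 0.201).

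Lists of metabolism and growth control genes held few calls. Of 32 components and regulators of mTORC1, the kinase complex that couples nutrients to growth, 0 passed (3 at an unadjusted p under 0.05, 0 by DESeq2), with log2 fold changes of -0.34 ± 0.18 for Ddit4 and -0.31 ± 0.10 for Mtor (camera adjusted p = 0.302). Of 26 glycolysis genes, 1 fell, the glucose transporter Slc2a1 (-1.12 ± 0.12, adjusted p = 0.00238), and 2 adjusted over the list alone (camera adjusted p = 0.174). Of 27 lysosome and autophagy genes, 1 fell, Neu1 (-2.07 ± 0.40), and 3 adjusted over the list alone (camera adjusted p = 0.308). Of 24 cholesterol synthesis and 12 fatty acid synthesis genes 0 passed (3 and 4 at an unadjusted p under 0.05, 0 and 0 by DESeq2). Adjusted over the list alone, 0 cholesterol genes passed, and 3 fatty acid genes fell and 1 rose (camera adjusted p = 0.140 for both lists, and 0.0481 for cholesterol synthesis without TAM-KO replicate 3, with 0.499 with an estimated correlation). Fry called the fatty acid list lower (adjusted p = 0.0457).

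Of 32 ribosome biogenesis and MYC target genes, 1 fell, the transcription factor gene Mycn (log2 fold change -0.68 ± 0.13), and 5 adjusted over the list alone, among them Mybbp1a (-0.38 ± 0.09) and Heatr1 (-0.42 ± 0.10). Camera called this list lower (adjusted p = 0.0273), with adjusted p = 0.624 with an estimated correlation, and no longer without TAM-KO replicate 4 (adjusted p = 0.764), Control replicate 3 (0.0763), or Control replicate 1 and TAM-KO replicate 4 together (0.376). Of 56 cytosolic ribosomal proteins 0 passed (7 at an unadjusted p under 0.05, 0 by DESeq2), with Rpl4 at -0.33 ± 0.11 (camera adjusted p = 0.0208, and adjusted p = 0.676 with an estimated correlation). The call was lost without Control replicates 2, 3 or 4 (adjusted p = 0.281, 0.0516 and 0.252) or TAM-KO replicates 1, 2 or 4 (0.0704, 0.0976 and 0.115). It held without Control replicate 1 (1.85e-07) or TAM-KO replicate 3 (0.000961), and without Control replicate 1 and TAM-KO replicate 4 together (1.06e-05, 7 members lower). Of 20 piRNA pathway genes 0 passed (5 at an unadjusted p under 0.05, 0 by DESeq2), with Mov10l1 at -0.29 ± 0.08 (camera adjusted p = 0.0273, and adjusted p = 0.371 with an estimated correlation), a call lost without Control replicate 3 (0.0635) or TAM-KO replicates 1 or 2 (0.106 and 0.140). Of 45 nuclear-encoded oxidative phosphorylation genes, 12 mitochondrially encoded proteins and 22 retinoic acid genes 0 passed (3, 0 and 6 at an unadjusted p under 0.05; 1, 0 and 1 by DESeq2), and camera called none of these 3 lists (adjusted p = 0.140, 0.368 and 0.635). Camera did call the nuclear-encoded list higher without Control replicates 2 or 4 (0.0455 and 0.0214), and the mitochondrially encoded list lower without Control replicate 1 (0.0242); with an estimated correlation these were 0.752, 0.690 and 0.523.

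Of the 37 lists tested, camera called 21 (6 higher, 15 lower). With an estimated correlation it called 0 after adjustment (7 at an unadjusted p under 0.05), and when each library was left out in turn it again called 0 (lowest adjusted p = 0.147). Fry called 10, all lower: 9 of the 21 and the fatty acid list. It called 0 of the 6 higher lists (adjusted p = 0.107 to 0.514). The unstranded counts leave 10 of the 43 named called genes with an annotated exon overlap, among them Gfra1, Bcl6, Fbxo32, Plk1, Sall4, Tlr3, Slc2a1 and Ccnd2. Reads of the overlapping part cannot be told from those of the other gene. Ambiguous reads were a class of their own (3.80% to 6.45% per library), so such reads may be missing from both genes.

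**Figure D3:**
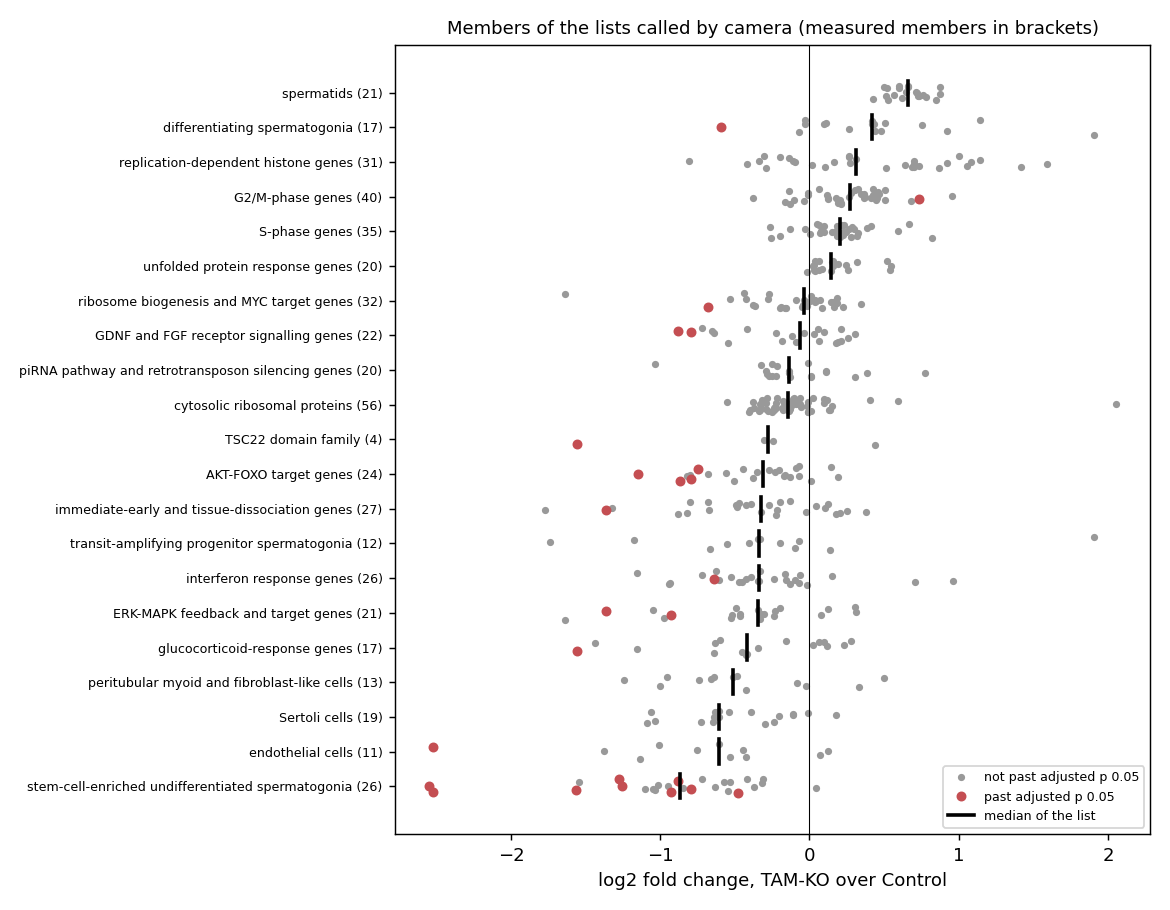
Log2 fold change (TAM-KO over Control) of each measured member of the 21 lists called by camera, with 1 row per list, red points for genes past the adjusted p of 0.05, grey points for the others and a black bar for the list median. The medians run from -0.86 for stem-cell-enriched spermatogonia to 0.66 for spermatids, and the spermatid list holds no red point.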

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

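The tests of spermatid markers, of untranscribed background and of dilution by other cells were chosen after the results they concern had been seen. A value was singled out when 1 library of a group lay far from the other 3: 23 of 438 such checks met this, against 21.9 expected by chance, so single entries are weak evidence. In Control replicate 1, Neurog3 (13.22 CPM), Dusp6 (40.56), Hsp90ab1 (1456), Ddx4 (340.6) and the summed ERK-MAPK list (881.2) were low and Lrp8 (31.29) was high. In Control replicate 2, Tcf7l1 was high (18.37 CPM). In Control replicate 3, Tsc22d4 (32.49 CPM) and Ldhb (16.48) were low and Met (41.54) and Heatr1 (802.5) were high. In TAM-KO replicate 3, Scd2 (80.7 CPM) and the summed progenitor (1372), AKT-FOXO (2652), ribosomal protein (9763) and interferon (493.0) lists were high, while Stip1 (131.7) and Pik3r1 (22.4) were low. In TAM-KO replicate 4, Tsc22d1 (271.9 CPM), Odf1 (868.3), Acrv1 (174.4) and the summed spermatocyte (3617) and spermatid (11440) lists were high.

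TAM-KO replicate 4 lay apart from the other 7 libraries on the first principal component (31.8% of the variance). Deeper sequencing is argued against: after thinning to 8462719 counts its distance was still 2.52 times that of the next farthest library. RNA of spermatocytes and spermatids is a candidate source: 21 of 21 spermatid markers had their highest CPM there. Whether it came from cells that passed the gate or from free RNA was not tested. Untranscribed background stays open, since 26.2% of its reads fell outside annotated features, against a median of 25.7% and a highest value of 30.2% in the others, while its summed olfactory and vomeronasal receptor CPM was the highest, at 146 against 60.6 to 108. No biological difference between this mouse set and the others was tested.

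Lower calls outnumbered higher calls, at 77.7% of 130. A length or GC trend as the whole source is argued against, because 98 of 101 lower calls stayed and 69.6% of calls were lower once it was removed. A part for it stays open, as the calls became 126 lower and 55 higher. Median exon length was 6374 for lower calls, 5197 for higher calls and 4317 for all tested genes. Scaling is argued against too (77.2% to 89.5% lower under the other scalings). A part of TAM-KO replicate 4 in the excess stays open: without it 56.6% of 415 calls were lower, which met the bound set beforehand for this source (at most 60%). That bound was set aside after the value was seen, because lower calls rose too, from 101 to 235, beside higher calls from 29 to 180. Loss of Gilz, in the sorted cells or in other cells, or the Cre transgene that shares its group, stays open for the genes themselves.

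The fall of stem-cell-enriched markers was weighed as a loss of spermatogonial RNA to other cells and as a length or GC trend. Dilution by cells that express neither set of markers would, alone, lower markers of differentiating spermatogonia as well. The median log2 fold change of the differentiating list was instead 0.42, against -0.86 for the stem-cell-enriched list. A permutation test of list members gave p = 1e-05, the smallest that the permutations can give. It treats members as independent, though they move together (estimated correlation 0.23 in the stem-cell-enriched list and 0.13 in the differentiating list). Dilution by differentiating spermatogonia, or by later germ cells that express some of the same markers, need not lower these markers. These values do not address it. A rise of differentiating markers could also offset a dilution by other cells, so dilution is not excluded. After the length and GC trend was removed, 9 of 9 falling markers stayed called. A smaller share of stem-type cells and a lower level per cell, each from loss of Gilz or from Cre, cannot be told apart in bulk RNA. Beforehand, a smaller share was to show as an SD among the 9 markers no larger than their mean SE, and to be ruled out above 2 times it; the value was 3.09 times. That bound was set aside after the value was seen, as wrong from the design: the remaining spermatogonia express each marker to a different degree, so a smaller share need not lower all by 1 factor.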

How the results depend on the processing

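Leaving out Control replicate 1 and TAM-KO replicate 4 together, leaving Tsc22d3 out of the lists, estimating the correlation with each library left out, and removing the length and GC trend were chosen after seeing the data. Tsc22d3 kept its fall and call in all 19 alternatives (log2 fold change -1.63 to -1.49, over leave-one-out fits too). The 130 genes called became 219 with upper-quartile scaling, 544 (350 lower, 194 higher) with DESeq2, 532 (353 lower, 179 higher) with limma-voom and library quality weights, 381 at an adjusted p under 0.1, and 628 (382 lower, 246 higher) without both libraries; leave-one-out fits gave 16 to 415. All 130 were among those called with quality weights and without both libraries, and 129 with DESeq2. The 9 stem-cell-enriched markers became 5 with limma-voom and 16 without both libraries, and 1 to 12 when 1 library was left out. The 21 lists called by camera became 0 with an estimated correlation (0 also with each library left out), 10 with fry (0 higher, 10 lower, 9 of them among the 21) and 20 of 36 with Tsc22d3 left out of the lists, and 14 to 22 when 1 library was left out. The replicate block gave 48 genes (40 lower) and 4 stem-cell-enriched markers. It ended the camera calls of the TSC22 (adjusted p = 0.0634), ribosome biogenesis (0.0533), GDNF and FGF (0.0511) and piRNA (0.0553) lists. Same-numbered libraries had correlations of -0.19, 0.11, 0.19 and -0.10, and 2 of 4 TAM-KO libraries correlated best with their own number. So few values cannot settle whether the numbers pair the samples, and the labels do not say. Itga6, never called, turned from 0.05 to -0.0055 with upper-quartile scaling, -0.0032 without Control replicate 1 and -0.029 without TAM-KO replicate 3 (-0.029 to 0.12 when 1 library was left out). No other named gene changed sign. Fewer libraries in the leave-one-out fits lower the power; the cause of the other shifts was not tested. At this depth and replication, 48 of 100 simulated 2-fold changes were recovered.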

Other observations

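Some gene groups were looked at after their members had been seen among the called genes, so their tests describe these libraries and are not independent evidence. Genes of basement membrane proteins leaned lower in TAM-KO: of 26 measured, 4 fell, Lamb1 (a laminin chain, log2 fold change -0.70 ± 0.11), Nid1 (nidogen, -0.76 ± 0.15), Fras1 (-0.95 ± 0.16) and Hmcn1 (hemicentin, -1.17 ± 0.21), and 0 rose. Camera gave adjusted p = 0.000765 over the 3 groups tried, with adjusted p = 0.188 with an estimated correlation. Marker lists of somatic testis cells also had medians below 0: -0.60 for Sertoli cells (18 of 19 members below 0), -0.61 for endothelial cells and -0.51 for peritubular myoid and fibroblast-like cells. The cells in which these genes fell are therefore not known. Of 13 tubulin genes, 2 rose, Tubb4b (0.76 ± 0.09, from 285 ± 20.3 to 482 ± 15.3 CPM, SD, n = 4 each) and Tuba3b (0.59 ± 0.09), beside Foxm1 (0.61 ± 0.10), a transcription factor of mitotic genes. Reads of near-identical tubulin copies can map to several of them. For the tubulins camera gave adjusted p = 0.0186, and adjusted p = 0.260 with an estimated correlation. Of 36 imprinted genes, Grb10 rose and Impact fell (-1.28 ± 0.18), and 20 had a log2 fold change below 0 (camera adjusted p = 0.0239, and adjusted p = 0.188 with an estimated correlation).

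Of the 101 genes that fell, 9 lie on the X chromosome, against 4.02 expected from the genes tested (Fisher's exact p = 0.0191, adjusted 0.419 over 22 chromosomes). The 9 include Tsc22d3, the deleted gene, which was not left out of this test. Among these 9, named after their values were seen, Zmym3 fell from 387 ± 16.1 to 164 ± 27.3 CPM (SD, n = 4 each) and Igbp1 had a log2 fold change of -1.39.

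Chance is argued against as the source of the 130 calls as a whole, but is not excluded. Of the 35 splits of the 8 libraries into 4 and 4, 1, the real one, called that many, and the highest of the others called 1. This is the smallest share that 35 splits can give. The other splits mix the groups, so any difference between the groups widens their spread and lowers their counts. The splits do not tell how many of the 130 calls are false.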
